A study of Homo sapiens with 6 samples.

How the data were processed

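RNA-seq libraries from 6 cultures of HMEC-1 cells were compared, 3 with an shRNA against SETD7 (Set7KD) and 3 with a non-targeting shRNA (NTC). Group and replicate number were taken from the sample titles, and the series' design text calls the libraries biological triplicates; whether they came from separate transductions is not given in the sources used here, so p-values measure the spread between these libraries. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit, poly-A RNA was selected on Dynabeads, and libraries were made with an Illumina mRNA-seq kit. The submitters' processing notes name BWA, bedtools and the genome build hg19, with no version of either tool. The values are read counts per gene, as whole numbers without normalization, which the authors deposited as 1 table with versioned Ensembl identifiers and gene symbols. Every listed gene had a sum of at least 60 counts over the 6 libraries. BWA does not splice reads, and the table's final row, for reads outside annotated genes, held 55.6 to 56.1% of the counts of each library; it names no gene and was kept out of library sizes and tests. Whether the counting used strand, and how it treated reads with several matches, is not given in the sources used here.

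Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM normalization, glmQLFit with robust estimation and glmQLFTest, groups as the single factor), and p-values were adjusted by the Benjamini-Hochberg method over the 18482 genes left by the filter. Genes with an adjusted p under 0.05 were called. CPM were computed from TMM-scaled library sizes, and the standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. Depth was 16385878 to 16953331 gene counts per library. Pairs of libraries of the same group differed by more than counting noise (chi-square over degrees of freedom of 2.98 to 9.85). None was therefore the same library sequenced again, but a second library from the same culture could not be told apart this way. The common biological coefficient of variation was 0.0688.

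Before the data were examined, 40 gene lists, the tests, the alternatives and a naming rule were fixed. The rule names SETD7, the 12 genes with the largest and the 12 with the smallest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap of CPM between the groups, and up to 4 members with the smallest p of each list described; members that did not pass may be named with their values. COL1A1, named beside its list, and the groups and genes of the closing paragraphs lie outside the rule and were chosen after their values were seen. Of 901 distinct list members written, 819 matched a row of the table. Lists were tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01, two-sided), adjusted over the 39 lists with at least 5 tested members. The 40th list, markers of lymphatic endothelium, had too few. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. None of the 39 lists passed with an estimated correlation, and the lowest adjusted p was then 0.073.

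The groups share replicate numbers, so it was checked whether the numbers pair the libraries. Over 11151 genes with a mean of at least 10 CPM, deviations from the group means correlated at 0.3, 0.42 and 0.34 between libraries with the same number, and at -0.36 to -0.04 between libraries with different numbers. By the rule fixed for this check, a correlation over 0.1 in every pair, the numbers were taken to pair the libraries. Deviations cancel within a group, so the negative values follow from the positive ones and add no evidence. With 3 libraries per group few matchings exist, so the observed one can be the best by chance, and the pairing is not certain. The pairing comes from the data, since no label says what a number stands for. A fit with the replicate number as a block was run beside the unblocked one.

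The alternatives were relative log expression and upper-quartile normalization, no filter, a filter of at least 50 counts in every library of a group, the replicate block, DESeq2 1.42.0, limma-voom, a test against a fold of 1.2, an adjusted p under 0.01, and each library left out in turn. Leaving out both libraries with the same number, keeping protein-coding genes and leaving out genes with a seed match were added after the data were seen. Gene types, transcript lengths, GC content and 3′ UTRs were taken from GENCODE 29 for 17753 of the 18544 genes, by Ensembl identifier without version. That annotation is on a later genome build than the counts, so no coordinates are given. Fold changes were also looked at along chromosomes while the tests were being chosen; this is not reported. Words of 7 bases in 3′ UTRs were scanned in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), by the t statistic of the presence of each word on the log2 fold change over 12367 protein-coding genes, with 200 shuffles of the genes. Reads shared between near-identical genes (HLA genes, metallothioneins, actins, histones and ribosomal proteins with their pseudogenes) could not be separated from the table.

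The steps were tested on 5 simulated count tables for the Set7KD and NTC libraries, drawn for the listed genes at the measured means, dispersions and library sizes with 200 changed genes each and about 18397 genes past the filter. On average edgeR called 62.0% of genes changed by a fold of 1.5 and 87.2% of genes changed by a fold of 2. The median error of the log2 fold change was 0.006, and 0 unshifted gene lists were called. Only means, dispersions and library sizes were carried over from the data. The list result therefore cannot speak to correlation between genes or to pairing by replicate number. Unchanged genes made up 10.0% of the calls on average (6.8 to 14%), which is more than the nominal share, so the counts of called genes are to be read as approximate. Each table held 200 changed genes, against 6690 genes called in the data, so this share may differ in the data.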

Results

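Poly-A RNA was sequenced from HMEC-1, an immortalised human dermal microvascular endothelial cell line, kept in MCDB131 medium at 5.5 mM glucose. The cells had received a lentivirus with either an shRNA against SETD7, called Set7KD (n = 3), or a non-targeting shRNA, called NTC (n = 3). SETD7, also written Set7, is a lysine methyltransferase that places a single methyl group on lysine 4 of histone H3 and also methylates other proteins. The count table listed 18544 genes, and the total gene count per library ran from 16385878 to 16953331, so that a single count was worth 0.059 to 0.061 CPM, the library-scaled count unit used throughout. Mitochondrially encoded genes took 2.05 to 2.63% of gene counts. The comparison asks which transcripts differ when SETD7 is knocked down.

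SETD7 (ENSG00000145391.7) itself was measured first. Its level was 178 ± 2.18 CPM in NTC and 32.8 ± 9.59 CPM in Set7KD (mean ± SD, n = 3 each), a log2 fold change of -2.44 with a standard error of 0.21 and an edgeR adjusted p of 0.000927. The 3 Set7KD libraries held 15.6, 24.6 and 15% of the NTC mean. Every Set7KD value lay below every NTC value. An exact two-sided permutation test of the CPM gave p = 0.1, the smallest value that 3 libraries against 3 allow.

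Among 18482 genes tested with edgeR, 3250 were higher and 3440 were lower in Set7KD, which is 36.2% of the genes. Most of these differences were small, with a median absolute log2 fold change of 0.398. A fold of at least 2 was reached by 190 higher and 401 lower genes, and a fold of at least 4 by 22 higher and 37 lower genes. The CPM of the groups did not overlap for 47.4% of the genes, where chance gives 10%. Against a minimum fold of 1.2 the counts were 903 higher and 1314 lower. Without both replicate 1 libraries they were 1414 higher and 1562 lower.

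**Figure D1:**
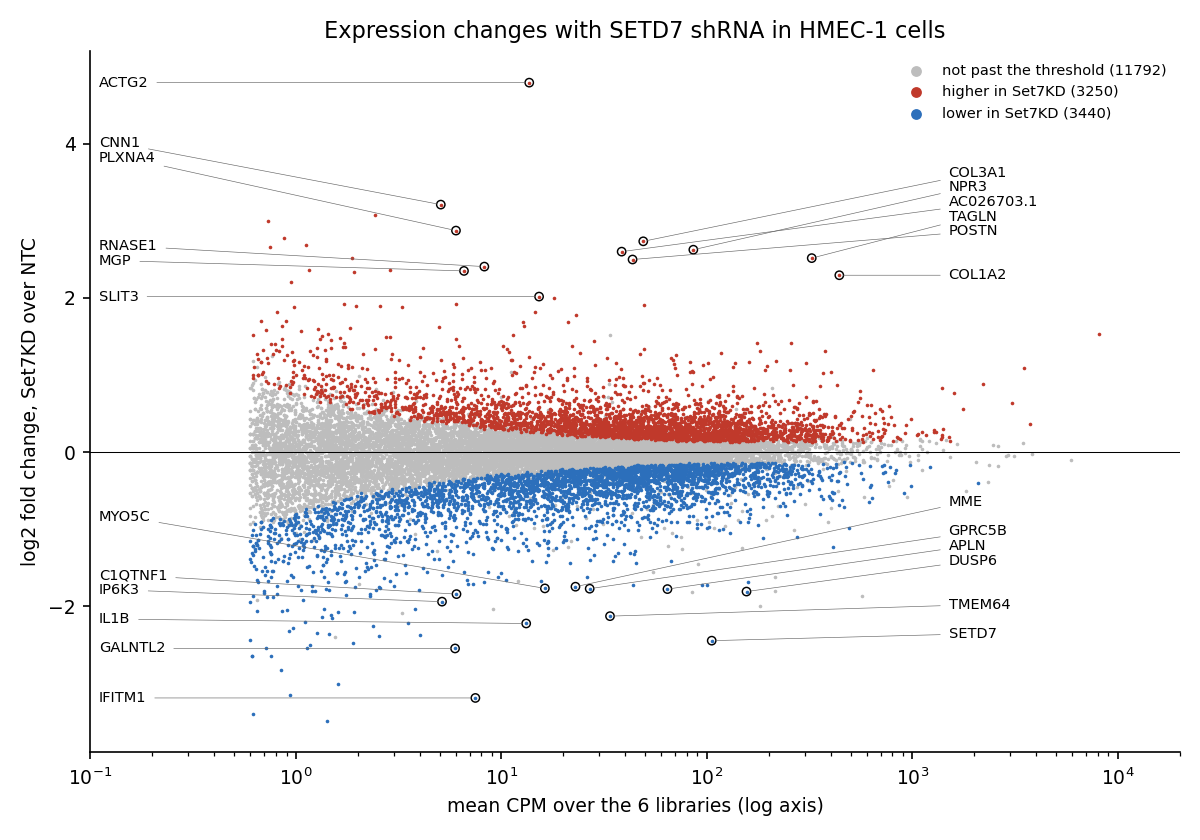
Log2 fold change (Set7KD over NTC, y axis) against mean CPM over the 6 libraries (log x axis) for the 18482 genes tested, each point a gene, with the 3250 higher genes in red, the 3440 lower genes in blue and the rest in grey. The circled genes are the 12 with the largest and the 12 with the smallest fold change under the naming rule, from ACTG2 at 4.79 to IFITM1 at -3.19.

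The genes with the largest rises included contractile and matrix genes. ACTG2, the gamma actin of smooth muscle, rose from 0.94 ± 0.51 to 26.4 ± 7.32 CPM (SD, n = 3), a fold of 27.7. CNN1, the smooth muscle calponin, rose from 0.98 ± 0.48 to 9.16 ± 1.86 CPM and TAGLN, an actin-binding protein of smooth muscle, from 96.3 ± 16.8 to 551 ± 116 CPM. The fibrillar collagen genes COL3A1 and COL1A2 rose by folds of 6.66 and 4.91, and POSTN, which encodes the matrix protein periostin, by a fold of 5.65. COL1A2 reached 733 ± 98.8 CPM. MGP, an inhibitor of calcification in the vessel wall, rose by a fold of 5.1, although its 3′ UTR carried ATGAATC or TGAATCA, and RNASE1, a secreted ribonuclease, by a fold of 5.31. PLXNA4 and SLIT3, a semaphorin co-receptor and a secreted guidance ligand, rose by folds of 7.33 and 4.05. NPR3, the clearance receptor for natriuretic peptides, rose from 23.9 ± 8.03 to 148 ± 20.2 CPM. AC026703.1 completed the 12 genes with a fold of 6.07, but was not found in the annotation used here, so that reads shared with a neighbouring gene were not ruled out. Its CPM were 10.7, 6.98 and 14.92 in NTC and 76.17, 58.78 and 63.27 in Set7KD. Those of NPR3 were 23.57, 16.08 and 32.12 in NTC and 170.86, 132.89 and 139.89 in Set7KD. Both rows moved in step across the 6 libraries, so AC026703.1 may not be a signal separate from NPR3. The edgeR adjusted p of the 12 genes lay between 3.7e-11 for COL3A1 and 0.00624 for RNASE1. Leaving out both libraries of a replicate number raised it to as much as 0.0874 for POSTN, 0.0748 for NPR3, 0.0731 for MGP and 0.0533 for AC026703.1. These calls were then lost. ACTG2 shares most of its coding sequence with other actin genes, and its counts are uncertain to that extent.

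The genes with the largest falls included signalling and inflammatory genes. IL1B, which encodes the cytokine interleukin 1 beta, fell from 21.7 ± 4.84 to 4.66 ± 1.96 CPM (SD, n = 3). DUSP6, a phosphatase that switches off ERK, fell from 242 ± 93.2 to 69.2 ± 25.6 CPM. APLN, the gene for the vascular peptide apelin, fell from 99.5 ± 26.5 to 29.1 ± 10.4 CPM. IFITM1, an interferon-induced membrane protein, had the lowest log2 fold change, -3.19 with a standard error of 0.66. The other genes were GALNTL2, a glycosyltransferase gene, at -2.55, TMEM64 at -2.13, the inositol phosphate kinase gene IP6K3 at -1.94, C1QTNF1 at -1.84, GPRC5B at -1.77, the unconventional myosin gene MYO5C at -1.77 and MME, which encodes the peptidase neprilysin, at -1.75. SETD7 was the remaining member of the 12. Their edgeR adjusted p ran from 1.38e-07 for GALNTL2 to 0.0468 for DUSP6. Leaving out a single library raised the adjusted p of IFITM1 to as much as 0.0895, of DUSP6 to 0.144, of APLN to 0.0961 and of MME to 0.0574, and these calls were then lost. The libraries concerned were NTC replicate 1 and Set7KD replicates 1, 2 and 3 for IFITM1, NTC replicates 1 and 2 and Set7KD replicates 1 and 3 for APLN, every library except NTC replicate 3 for DUSP6, and Set7KD replicate 1 for MME. The annotated 3′ UTRs of SETD7, TMEM64, MYO5C, MME, DUSP6 and APLN contained the 7-base word ATGAATC or TGAATCA, the words most strongly associated with lower fold changes across genes.

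Matrix genes rose, and so did genes used as markers of fibroblasts and smooth muscle. Of 31 tested genes for extracellular matrix and basement membrane, 16 rose and 5 fell (17 and 5 when adjusted over the list alone), and camera gave an adjusted p of 7.45e-09 (adjusted p = 0.55 with an estimated correlation). SPARC, a collagen-binding glycoprotein, rose from 1181 ± 49.4 to 2005 ± 80.3 CPM and the proteoglycan gene VCAN from 122.7 ± 11.7 to 218 ± 7.7 CPM, beside COL3A1 and COL1A2. Among 10 fibroblast markers 5 rose and 0 fell by edgeR (5 and 0 adjusted over the list alone), and the camera adjusted p was 4.39e-11 (adjusted p = 0.073 with an estimated correlation). The 5 were COL3A1, COL1A2, POSTN, PDGFRA and COL1A1, and COL1A1 already stood at 1555 ± 270 CPM in NTC. All of them except PDGFRA also stood in the matrix list, so the fibroblast call rests largely on the same genes. Another fibroblast marker, LUM, did not pass, with 1.56 ± 0.13 CPM in NTC and 1.98 ± 0.16 CPM in Set7KD. Among 12 smooth muscle and pericyte markers 6 rose and 0 fell by edgeR (7 and 0 adjusted over the list alone), with a camera adjusted p of 6.95e-06 (adjusted p = 0.55 with an estimated correlation). The 4 with the smallest p were CNN1, ACTG2, TAGLN and LMOD1. ACTA2, the alpha actin of smooth muscle, had 38.2 ± 4.58 CPM in NTC and 43.9 ± 3.82 CPM in Set7KD, and MYH11, its myosin heavy chain, 10.6 ± 1.58 and 9.54 ± 0.72 CPM. Neither passed, with edgeR adjusted p of 0.0999 and 0.363. Of the written members of these lists, 6 matrix genes, 6 fibroblast markers and 5 smooth muscle markers also stood in another list.

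**Figure D2:**
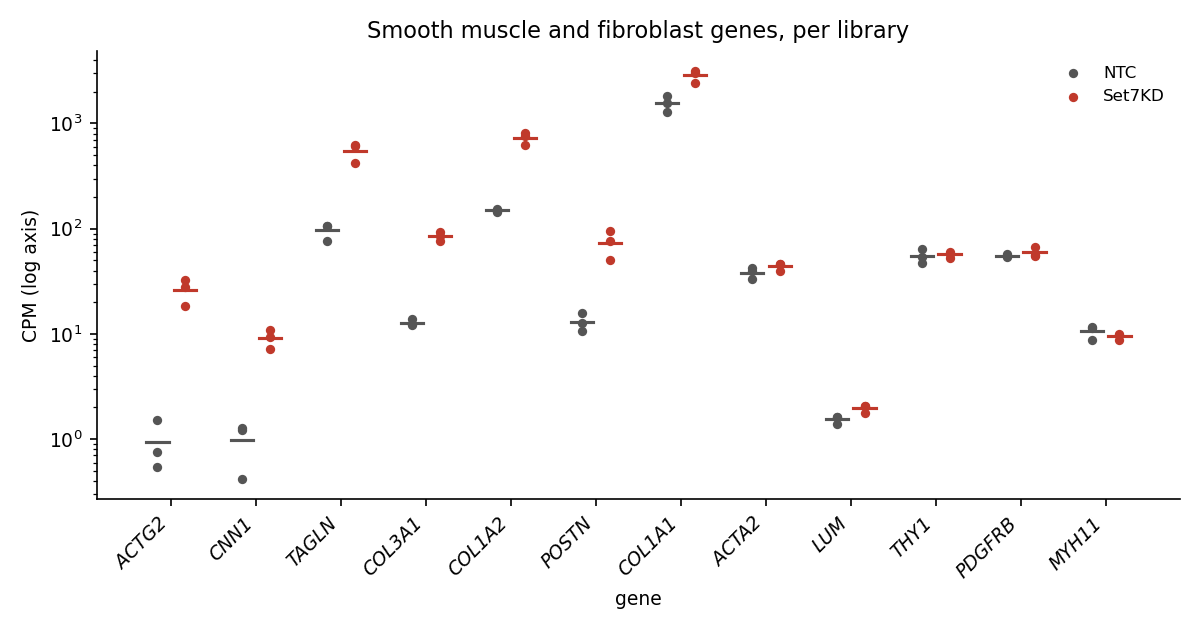
CPM (log y axis) of 12 smooth muscle, fibroblast and matrix genes in each library, NTC in grey and Set7KD in red, with a bar at each group mean (n = 3). ACTG2, CNN1, TAGLN, COL3A1, COL1A2, POSTN and COL1A1 were higher in every Set7KD library, while ACTA2, THY1, PDGFRB and MYH11 overlapped between the groups and LUM moved from 1.56 to 1.98 CPM.

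The genes of the actin cytoskeleton and of contractility rose as well. Of 28 tested members 19 rose and 3 fell (20 and 3 adjusted over the list alone), with a camera adjusted p of 3.3e-09 (adjusted p = 0.55 with an estimated correlation). TPM1, a tropomyosin that lies along actin filaments, rose from 417 ± 10.4 to 872 ± 87.2 CPM, and MYL9, a regulatory light chain of myosin, from 133 ± 9.55 to 301 ± 38.0 CPM. MYH10, a non-muscle myosin heavy chain, fell from 541 ± 32.1 to 338 ± 22.0 CPM, so that contractile genes did not all move in the same direction; its 3′ UTR carried ATGAATC or TGAATCA. The list shares 4 written members with other lists, and the smooth muscle markers CNN1, TAGLN and ACTG2 described above moved with it.

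Genes that respond to TGF-beta, a cytokine that induces matrix genes, gave a less firm result. Of 23 members 10 rose and 2 fell (10 and 2 adjusted over the list alone), with a camera adjusted p of 0.0171 (adjusted p = 0.61 with an estimated correlation). INHBA, an activin subunit, rose from 14.2 ± 1.98 to 27.3 ± 3.12 CPM and BAMBI, an inhibitory pseudoreceptor of this pathway, from 7.11 ± 0.43 to 12.1 ± 1.64 CPM, while TGFBI fell from 429 ± 28.9 to 290 ± 27.6 CPM. The 3′ UTRs of INHBA and TGFBI carried ATGAATC or TGAATCA. With the replicate block the count of lower members was 7 and the call was lost, with an adjusted p of 0.396. Without NTC replicate 3 the camera adjusted p was 0.101, and it reached 0.519 over all settings with libraries left out. In all, the TGF-beta list passed in 14 of 18 alternatives. Of 15 matrix proteases and their inhibitors 7 rose and 3 fell (7 and 3 adjusted over the list alone). This list did not pass camera, with an adjusted p of 0.0616, but passed with the replicate block at 0.0437 (adjusted p = 0.54 with the block and an estimated correlation) and with fry at 0.026. It also passed without NTC replicate 1, NTC replicate 3 or Set7KD replicate 2, and in 8 of 18 alternatives in all; its adjusted p lay between 0.0151 and 0.109 when libraries were left out. SERPINE2, a protease inhibitor, rose from 124 ± 12.3 to 269 ± 31.6 CPM, and the collagenase gene MMP1 fell from 22.8 ± 4.21 to 11.3 ± 1.85 CPM.

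Genes of the type I interferon response were lower in Set7KD. Of 29 members 12 fell and 0 rose by edgeR (13 and 0 adjusted over the list alone), and the camera adjusted p was 3.8e-05 (adjusted p = 0.69 with an estimated correlation). STAT2, a subunit of the transcription factor activated by interferon, fell from 105 ± 13.9 to 59.0 ± 4.08 CPM, and IRF7, an inducer of interferon genes, from 9.91 ± 1.03 to 4.92 ± 1.26 CPM. ISG20, an exonuclease gene, had a log2 fold change of -1.25 and USP18, a negative regulator of interferon signalling, of -1.17. The 3′ UTRs of STAT2 and USP18 carried ATGAATC or TGAATCA. The count of lower members was 22 without NTC replicate 3. With fry the interferon list and the MHC class I list were not called, each at an adjusted p of 0.097; with the replicate block fry gave 0.13 and 0.046. Genes of antigen presentation by MHC class I followed, with 8 of 15 lower and 2 higher (9 and 2 adjusted over the list alone) and a camera adjusted p of 0.0171 (adjusted p = 0.69 with an estimated correlation). HLA-E fell from 206 ± 17 to 110 ± 8.73 CPM, and PSMB10, a subunit of the immunoproteasome, had a log2 fold change of -0.38. ERAP1, a peptide-trimming peptidase, went the other way and rose from 136 ± 9.0 to 184 ± 8.71 CPM. HLA genes are near-identical copies whose reads the counting could have split, so their values are uncertain. Without Set7KD replicate 3 the MHC list had an adjusted p of 0.0531.

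Among 26 genes of the NF-kB and inflammatory response, 8 fell and 4 rose (8 and 5 adjusted over the list alone). NFKB2 and RELB, subunits of NF-kB, fell with log2 fold changes of -0.57 and -0.65, and BIRC3, an inhibitor of apoptosis, fell at -1.21. The chemokine gene CXCL5 rose from 3.18 ± 0.52 to 8.83 ± 0.64 CPM. The list did not pass camera, with an adjusted p of 0.16. With the replicate block 15 members were lower and 6 higher, and the list passed at 0.00274 (adjusted p = 0.64 with the block and an estimated correlation). It also passed without NTC replicate 3 or Set7KD replicate 2, and in 4 of 18 alternatives in all.

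Immediate early genes, which are transcribed within minutes of a stimulus, had the lowest median of the lists that passed, a log2 fold change of -1.23 over 27 members. The camera adjusted p was 0.000245 (adjusted p = 0.69 with an estimated correlation). The number of single genes called depended on how replicates were treated: 6 fell and 0 rose by edgeR (3 and 0 adjusted over the list alone), and 24 fell with the replicate block. JUN, a subunit of the transcription factor AP-1, fell from 573 ± 138 to 244 ± 33.8 CPM and JUND, a related subunit, from 102 ± 8.57 to 67.95 ± 6.02 CPM. KLF2, a flow-responsive endothelial transcription factor, fell from 52.7 ± 17 to 21.2 ± 2.2 CPM, and FOSL1 had a log2 fold change of -0.27. Within NTC, replicate 3 had lower levels than replicates 1 and 2 of these genes, and without that library 15 members were called lower. Leaving out any of the other libraries brought the count to 1 or 2, and the calls of JUN and KLF2 were then lost. With fry the list was not called, at an adjusted p of 0.097, but it was with the block, at 0.023. FOSL1 lost its call without NTC replicate 1, NTC replicate 2 or Set7KD replicate 1.

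**Figure D3:**
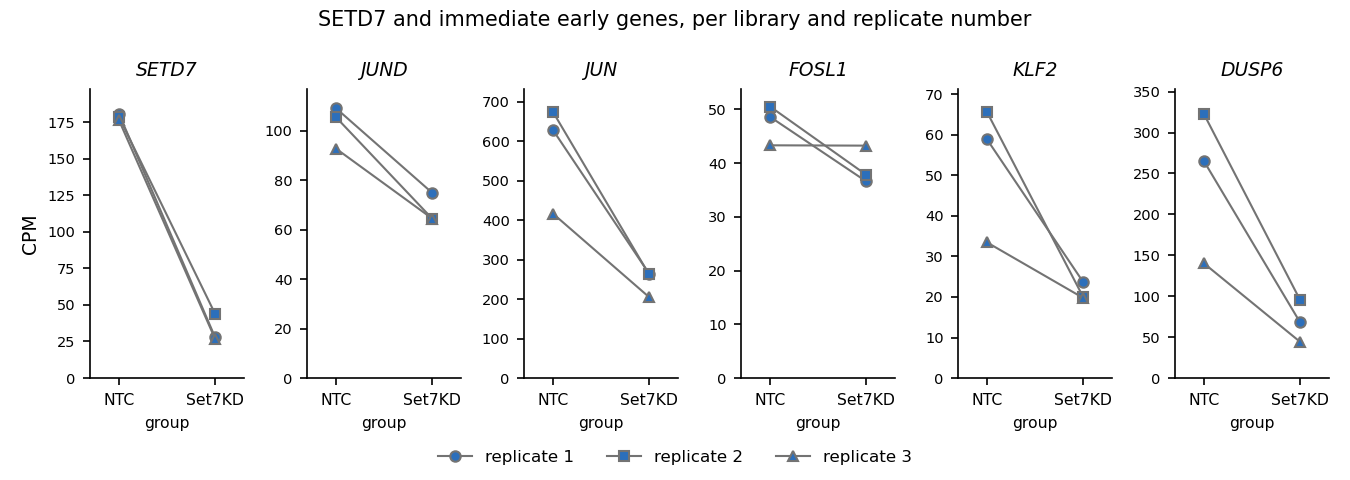
CPM (y axis, from 0) of SETD7 and 5 immediate early genes in each library, with a line joining the NTC and the Set7KD library of the same replicate number. JUN fell along each line, although NTC ranged widely around its mean of 573 CPM (SD 138), and FOSL1 was nearly level in replicate 3.

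Targets of p53, the tumour suppressor induced by DNA damage, were lower. Of 28 members 18 fell and 1 rose (20 and 1 adjusted over the list alone), with a camera adjusted p of 3.8e-05 (adjusted p = 0.69 with an estimated correlation). GDF15, a stress-induced cytokine, fell from 95.9 ± 14.2 to 45.2 ± 3.17 CPM, and BAX, which promotes apoptosis, from 119 ± 13.6 to 90.0 ± 1.76 CPM. SPATA18 and PHLDA3 had log2 fold changes of -1.12 and -0.53. The 3′ UTRs of SPATA18 and, below, CHAF1A carried ATGAATC or TGAATCA. The count of lower targets was 11 without NTC replicate 1 and 11 without Set7KD replicate 1, and with fry the list was not called, at an adjusted p of 0.097, but was with the replicate block, at 0.046. Cell cycle genes of G2 and mitosis gave 7 higher and 0 lower by edgeR among 30 (7 and 0 adjusted over the list alone), and 4 higher without NTC replicate 1. Their camera adjusted p was 0.255. Genes of DNA replication gave 11 higher and 8 lower among 35 (11 and 8 adjusted over the list alone), with a camera adjusted p of 0.581. CCNE1, the cyclin of S phase entry, rose from 5.66 ± 0.86 to 12.1 ± 0.59 CPM, and CHAF1A, a histone chaperone of replication, fell from 148 ± 3.73 to 109 ± 5.41 CPM.

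Many genes of protein folding rose, with median log2 fold changes of 0.28 and 0.21 in the lists below. Of 20 chaperones of the endoplasmic reticulum 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a camera adjusted p of 0.00019 (adjusted p = 0.55 with an estimated correlation). HSPA5, the main chaperone there, rose from 478 ± 20.8 to 728 ± 30.0 CPM and CANX, a lectin chaperone, from 661 ± 21.7 to 852 ± 30.6 CPM. EDEM1, which takes part in the disposal of misfolded glycoproteins, fell from 169 ± 3.79 to 120 ± 2.57 CPM. Of 18 heat shock proteins 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a camera adjusted p of 0.000208 (adjusted p = 0.55 with an estimated correlation). CRYAB, a small heat shock protein, rose from 6.45 ± 0.44 to 22.8 ± 3.89 CPM and HSPH1, with ATGAATC or TGAATCA in its 3′ UTR, from 160 ± 8.89 to 241 ± 5.2 CPM.

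Ribosome assembly genes and ribosomal protein genes moved in opposite directions. Of 25 genes of ribosome biogenesis and MYC targets 19 rose and 0 fell by edgeR (19 and 0 adjusted over the list alone), and the camera adjusted p was 1.83e-07 (adjusted p = 0.17 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, rose from 141 ± 10.7 to 239 ± 14.7 CPM, and NOLC1, a nucleolar protein, from 188 ± 4.27 to 267 ± 4.55 CPM. Of 45 cytosolic ribosomal protein genes 26 fell and 0 rose by edgeR (29 and 1 adjusted over the list alone), with a camera adjusted p of 3.71e-06 (adjusted p = 0.55 with an estimated correlation). RPL3 fell from 762 ± 16.2 to 506 ± 32.1 CPM and RPS14 from 333 ± 7.49 to 246 ± 7.46 CPM. The median log2 fold change was 0.26 in the first list and -0.2 in the second. Ribosomal protein genes have many processed pseudogenes that could have shared reads with them.

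Cholesterol biosynthesis and uptake had 7 lower and 1 higher of 25 (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.0382 (adjusted p = 0.73 with an estimated correlation). SREBF2, the transcription factor of this pathway, fell from 265 ± 33.0 to 185 ± 7.85 CPM. The call was lost with the replicate block, at an adjusted p of 0.0781, and with fry, at 0.21, and without the genes that have ATGAATC or TGAATCA in the 3′ UTR, at 0.0939. It was also lost without NTC replicate 3, Set7KD replicate 2 or Set7KD replicate 3, and the number of lower members was 15 without NTC replicate 2 and 4 without Set7KD replicate 3. In all, the list passed in 8 of 18 alternatives. Genes induced by ATF4, the transcription factor of amino acid shortage, had 11 lower and 3 higher of 22 (11 and 4 adjusted over the list alone), with a camera adjusted p of 0.036 (adjusted p = 0.61 with an estimated correlation). CHAC1, which degrades glutathione, fell from 6.77 ± 1.29 to 2.59 ± 0.54 CPM and ALDH1L2, a mitochondrial folate enzyme, rose from 7.77 ± 0.7 to 16.9 ± 1.75 CPM. This list did not pass without NTC replicate 2 or without Set7KD replicate 2, and passed in 12 of 18 alternatives. Glycolysis and glucose uptake did not pass camera (adjusted p 0.641), with 8 higher and 4 lower of 22 (8 and 5 adjusted over the list alone). LDHA, lactate dehydrogenase, rose from 422 ± 14.7 to 604 ± 14.8 CPM and ENO2, an enolase, fell from 94.97 ± 0.95 to 58.1 ± 3.34 CPM. ENO2 and ALDH1L2 carried ATGAATC or TGAATCA in the 3′ UTR. The number of higher glycolysis genes was 5 without NTC replicate 2, NTC replicate 3 or Set7KD replicate 1. Nuclear genes of oxidative phosphorylation had 10 higher and 2 lower of 36 (10 and 2 adjusted over the list alone) at a camera adjusted p of 0.134, and passed with fry at 0.02.

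**Figure D4:**
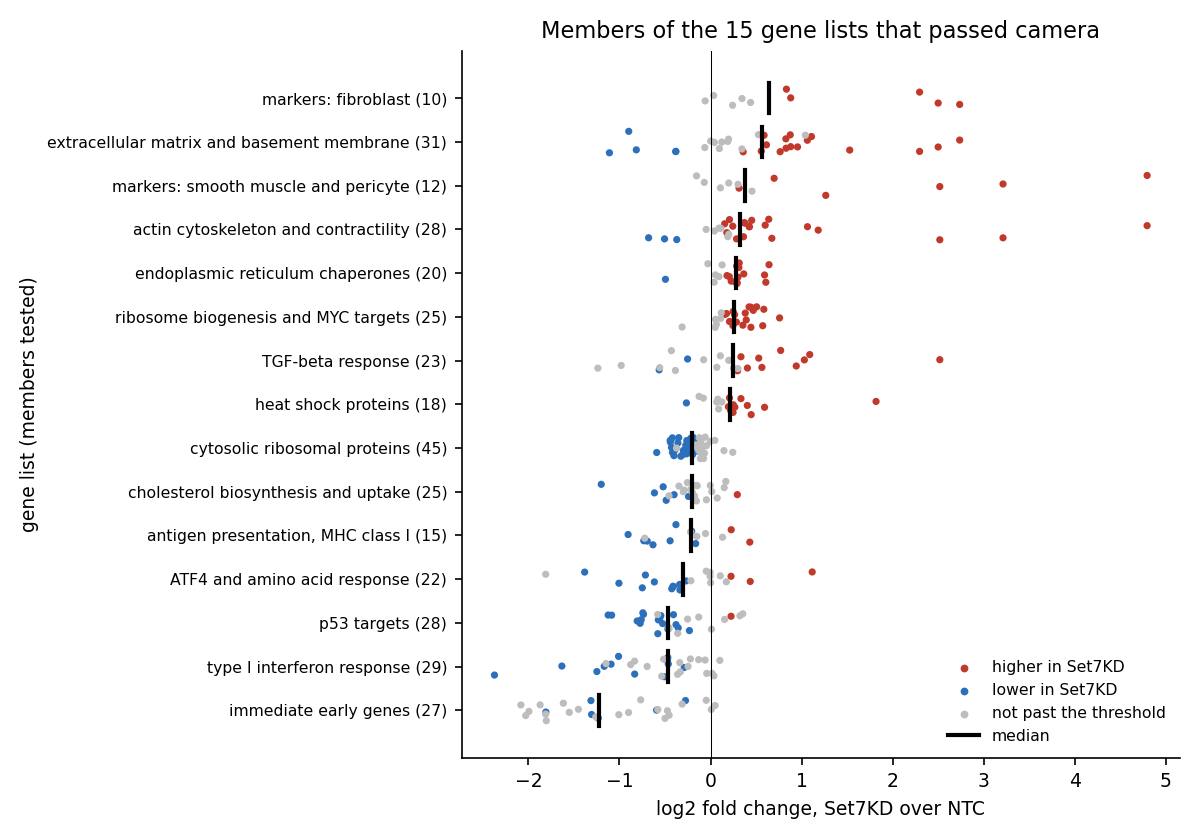
Log2 fold change (Set7KD over NTC, x axis) of each tested member of the 15 gene lists that passed camera (y axis, with the number of members), higher genes in red, lower genes in blue, others in grey, and a black bar at each median. Medians ran from 0.64 for fibroblast markers to -1.23 for immediate early genes.

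Endothelial identity genes changed in both directions. Of 28 members 8 rose and 6 fell (8 and 6 adjusted over the list alone), and the camera adjusted p was 0.853. TIE1, an endothelial receptor kinase, fell from 144 ± 6.74 to 87.3 ± 3.48 CPM and TAL1, a transcription factor, from 35.5 ± 0.61 to 24.8 ± 2.92 CPM. PTPRB, the endothelial receptor phosphatase, rose from 24.4 ± 3.02 to 36.2 ± 1.07 CPM, and PLVAP, a protein of endothelial fenestrae, from 0.93 ± 0.21 to 4.79 ± 1.82 CPM. Angiogenic receptors and ligands had 7 higher and 12 lower of 28 (9 and 15 adjusted over the list alone), with a camera adjusted p of 0.404. EFNB2, an arterial ephrin, rose from 38.7 ± 2.43 to 75.6 ± 5.22 CPM, and the VEGF co-receptor gene NRP1 from 142 ± 7.53 to 215 ± 8.44 CPM. Notch signalling had 7 higher and 5 lower of 20 (7 and 5 adjusted over the list alone), with a camera adjusted p of 0.179. Without the genes that have ATGAATC or TGAATCA in the 3′ UTR the Notch list passed, at 0.0454. The ligand gene JAG1 rose from 63.0 ± 4.79 to 140 ± 13.2 CPM, while the ligand gene DLL4 fell from 3.12 ± 0.91 to 0.73 ± 0.37 CPM. The number of lower Notch genes was 3 without NTC replicate 1, NTC replicate 2, Set7KD replicate 2 or Set7KD replicate 3. Integrins and junction genes had 8 higher and 6 lower of 27 (9 and 6 adjusted over the list alone) at a camera adjusted p of 0.208. ITGA4 rose from 56.0 ± 6.45 to 115 ± 4.49 CPM, ITGB4 fell from 72.0 ± 7.05 to 33.7 ± 4.2 CPM, and CDH11, a mesenchymal cadherin, rose from 2.51 ± 0.52 to 9.56 ± 1.22 CPM. The list passed with fry, at an adjusted p of 0.006. The 3′ UTRs of PTPRB and CDH11 carried ATGAATC or TGAATCA, although the genes rose.

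The chromatin lists and the list of reported SETD7 substrates did not pass camera. Of 31 histone lysine methyltransferases other than SETD7, 13 fell and 3 rose (13 and 3 adjusted over the list alone), with a camera adjusted p of 0.179. EZH1 fell from 54.3 ± 1.98 to 37.5 ± 1.32 CPM and its paralogue EZH2 rose from 72.5 ± 4.83 to 99.2 ± 1.52 CPM. Of 18 lysine demethylases 5 fell and 3 rose (5 and 3 adjusted over the list alone), at a camera adjusted p of 0.467. Of 14 genes of DNA methylation and its removal 3 rose and 0 fell by edgeR (3 and 0 adjusted over the list alone), at a camera adjusted p of 0.388, and the 3 were DNMT3B, MBD2 and TDG. Of 20 genes whose proteins are reported SETD7 substrates 7 fell and 3 rose (7 and 3 adjusted over the list alone), with a camera adjusted p of 0.25. YAP1, a coactivator of the Hippo pathway, fell from 237 ± 1.49 to 160 ± 16 CPM, KAT2B, a histone acetyltransferase, from 43.9 ± 5.0 to 26.5 ± 1.26 CPM, and HIF1A, a hypoxia-inducible factor, rose from 391.5 ± 19.1 to 499 ± 30.0 CPM. YAP1, KAT2B and, among the risen genes, MBD2 carried ATGAATC or TGAATCA in the 3′ UTR. With fry the lists of methyltransferases, demethylases and DNA methylation passed, at adjusted p of 0.006, 0.0076 and 0.02 (0.054, 0.036 and 0.063 with the replicate block). Of 23 target genes of YAP and TAZ 8 rose and 5 fell (8 and 7 adjusted over the list alone), at a camera adjusted p of 0.945, and 9 fell with the replicate block. Without Set7KD replicate 1 there were 5 higher YAP and TAZ targets, without NTC replicate 3 there were 9 lower ones and without Set7KD replicate 2 there were 3.

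Markers of epithelium and leukocytes, cell types that the cultures should not hold, did not pass camera. Of 7 epithelial markers 3 fell and 0 rose by edgeR (4 and 1 adjusted over the list alone), and of 5 leukocyte markers 3 fell and 0 rose (3 and 2 adjusted over the list alone), at camera adjusted p of 0.356 and 0.275; with fry the leukocyte list passed as lower, at 0.033, but not with the replicate block, at 0.12. Of the tested genes, 13056 were protein-coding and 5552 of these were called. Among 2555 pseudogenes 522 were called, and among 1337 antisense genes 273. No source used here states that counting took strand into account, so antisense genes cannot be told from their partners and pseudogenes may share reads with parent genes; both sets of calls are uncertain.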

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

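Leaving out both libraries with the same replicate number, keeping protein-coding genes and leaving out genes with a seed match were chosen after the data were seen; the other alternatives were planned. SETD7 remained lower and called in all 17 of its alternatives, with log2 fold changes of -2.71 to -2.31 and an adjusted p of at most 0.0177. The counts of 3250 higher and 3440 lower genes moved by more than 1.5 times with an adjusted p under 0.01 (2103 and 2197), against a fold of 1.2 (903 and 1314) and without both replicate 1 libraries (1414 and 1562); the first 2 are stricter by construction, and in the last the cause was not tested. Without 1 library they were 2423 to 3214 and 2545 to 3303, and without both libraries of a number 1414 to 3037 and 1562 to 3113. DESeq2 gave 2712 and 2688, and limma-voom 3238 and 3403. The replicate block, for which the libraries were paired by number, gave 3826 higher and 4090 lower genes, and 6671 genes were called in both fits, all with the same sign; for the lists it gave 8 and 7. It ended the calls of the TGF-beta and cholesterol lists, added those of the NF-kB list and the matrix proteases, and changed no other camera call of a list. In this paragraph, named genes include up to 4 members of every tested list, also of lists not described above. Among them the block ended the call of THBS1 (adjusted p 0.0559) and added those of WNT5B, TLE1 and CORO1A. The 8 lists called higher and 7 called lower became 0 and 0 with camera and an estimated correlation, which was the highest adjusted p among the 18 alternatives of each of the 15 lists; fry gave 12 and 5, but not the same lists: it ended the calls of the interferon, MHC class I, p53 and immediate early lists (0.097 each) and of cholesterol (0.21), and added methyltransferases, demethylases and leukocyte markers as lower and proteases, adhesion, DNA methylation and oxidative phosphorylation as higher. With the replicate block fry called MHC class I and p53 (0.046 each), immediate early (0.023), YAP and TAZ (0.023), NRF2 (0.015) and SETD7 substrate (0.036) lists, and no longer TGF-beta (0.38), ATF4 (0.054), methyltransferases (0.054), DNA methylation (0.063) or leukocyte markers (0.12). Without 1 library the lists numbered 8 to 10 higher and 5 to 8 lower, and without both libraries of a number 9 to 10 and 7 to 8. Without both replicate 1 libraries fewer members of many lists were called, among them 4 lower p53 targets, 5 interferon genes, 1 MHC class I gene and 12 ribosomal protein genes, and 0 higher G2 and mitosis genes with edgeR, 1 DNA replication gene, 1 YAP and TAZ target, 11 ribosome biogenesis genes, 5 heat shock genes, 3 fibroblast and 3 smooth muscle markers. The other pairs moved counts both ways: without replicate 3, 24 immediate early, 23 interferon and 14 NF-kB genes but 7 methyltransferases were lower and 7 DNA replication genes higher, and without replicate 2, 17 cholesterol genes but 1 immediate early gene, 2 YAP and TAZ targets and 2 Notch genes were lower. Over the alternatives the adjusted p ran from 0.000238 to 0.613 for the TGF-beta list, 1.06e-06 to 0.729 for cholesterol, 0.000253 to 0.745 for NF-kB and 0.0151 to 0.548 for the proteases. No called list and no named gene reversed. Of the 160 called genes in this wider set of named genes, 11 lost the call without some single library and 26 without some replicate number. At this depth, genes near the filter show only large changes.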

Other observations

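The groups of genes in this paragraph and the next were chosen after the data were seen. All 4 metallothionein genes tested, whose proteins bind zinc and copper, were lower in Set7KD. MT2A fell from 241 ± 27.6 to 75.4 ± 14.1 CPM (SD, n = 3) and MT1E from 39.0 ± 2.1 to 14.8 ± 1.26 CPM, with edgeR adjusted p of 0.000629 and 3.67e-08; these are close paralogues, so reads could be split among them. Of 17 genes that ERK signalling induces, 7 were lower and 0 higher by edgeR, and 13 were lower with the replicate block. Of the 7, DUSP6 and SPRED2 dampen ERK signalling, while ETV1, ETV4, ETV5, MAFF and FOSL1 encode transcription factors. The other dampening genes, DUSP4, DUSP5, SPRY1, SPRY2, SPRY4, SPRED1 and SPRED3, did not pass without the block. With it, DUSP4, DUSP5, SPRY2 and SPRY4 were also called lower. Beside DUSP6, ETV4, with ATGAATC or TGAATCA in its 3′ UTR, fell from 9.65 ± 1.41 to 4.47 ± 1.22 CPM and ETV5 from 60.8 ± 3.38 to 37.5 ± 4.07 CPM, while SPRY1 had 16.5 ± 3.81 and 16.6 ± 2.99 CPM.

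Of 30 semaphorin, slit, plexin, neuropilin and robo genes, which guide axons and vessels, 9 rose and 10 fell. SEMA3D rose from 28.1 ± 1.78 to 71.2 ± 6.01 CPM and SEMA3C from 67.5 ± 5.6 to 122.8 ± 0.97 CPM, while SEMA3B fell from 12.8 ± 0.7 to 5.34 ± 0.46 CPM. Of 9 genes grouped here as imprinted and paternally expressed, IMPACT among them, 3 rose and 2 fell. Whether each is imprinted in these human cells was not tested. MEST rose from 98.4 ± 3.38 to 222 ± 10.3 CPM and PEG10 from 123.4 ± 8.19 to 259 ± 8.63 CPM. The lymphatic markers PDPN, FLT4 and CLU had log2 fold changes of -0.35, -0.48 and -0.51. Each pair was also compared with the other 2, over genes called in those with an absolute log2 fold change of at least 1. The slope of a pair's fold changes on those of the other pairs was 0.883 for replicate 1 (437 genes), 0.671 for replicate 2 (660 genes) and 0.789 for replicate 3 (648 genes). Choosing genes by their fold change in the other pairs can lower a slope, and the genes differ between pairs. The slopes therefore cannot be set against how much SETD7 each library held.

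In the paragraphs below, the test of cells of another type, including its bound of 0.1, was chosen after the result was seen, as were the 8-base word and the counts by class of match; the first replaced a test by endothelial identity genes (8 rose and 6 fell), also chosen after, and the seed and pseudogene tests were written before they were run but prompted by single genes among the largest changes. Whether the numbers of called genes can arise from any grouping was examined over the 10 splits of the 6 libraries into 3 and 3. With so few splits the share with a result as large cannot go below 0.1. The real split gave 3250 higher and 3440 lower genes with edgeR, and the highest of the other splits gave 0 and 0, with 271 higher and 513 lower genes at an unadjusted p under 0.05; no other tool was run on the splits. Thus 1 of the 10 splits, the real one, gave as many. The 3 other splits that part all 3 pairs of replicate numbers also gave 0 and 0, and the remaining splits part 1 pair. Every split except the real one mixes libraries of both groups on each side. The difference between the groups then widens the spread within each side, which made few calls likely in advance. The splits therefore cannot decide this question.

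The lower genes carried a sequence pattern of the kind that a short hairpin RNA leaves when its seed pairs with other transcripts. Of 16224 words of 7 bases in 3′ UTRs, ATGAATC had the lowest t for association with the log2 fold change, -13.64 (-13.65 with the replicate block). TGAATCA was second, and words that share part of them followed (GAATCAT at -9.05, TGAATCT at -7.93). The 5% point of the lowest t under shuffling was -4.3, taken over only the 5357 words that occur in the SETD7 transcript. AU-rich words such as TATTTAT (-5.91) also lay below it, though TATTTAT and GAATCAT are not among those words. The highest t, 4.34, lay under its 95% point of 4.48, which was taken over all words. ATGAATC and TGAATCA both lie within ATGAATCA, which occurs once in the coding sequence of the SETD7 transcript used here. The 3′ UTR of that transcript holds 2 matches of 7 bases. An occurrence there is weak evidence alone, as 33.0% of the words tested occur in that transcript. Of 475 genes with ATGAATCA in the 3′ UTR 41.1% were lower and 13.7% higher, against 20.6% and 22.1% of 10192 genes with no match, and 13 of the 20 lower genes with the highest F statistic had a match, PPP1CA (log2 fold change -1.72), CASC4 (-1.41) and RPS6KB1 (-1.19) among them. A candidate explanation for these genes is silencing by the SETD7 hairpin through its seed, independent of SETD7; the hairpin sequence is not known here, and a microRNA that responds to SETD7 would leave the same pattern, which was not tested. The excess of lower genes with a match is about 205 of the 2757 lower genes scanned. It may be too low because genes with only a shorter match are in the comparison class. It may also be too high, since these shares, unlike the word scan, took no account of 3′ UTR length, base content or expression. Without genes that have a match 2882 genes were higher and 2775 lower. Of the lists, 9 were then called higher (Notch signalling added) and 6 lower (cholesterol lost). The excess and this fit take account only of genes that carry a match themselves. Genes that changed in response to those would carry no match and stay in both. Neither result therefore limits how many genes or lists such silencing could have changed.

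Smooth muscle, fibroblast and matrix genes rose in endothelial cultures, and cells of another type or a bias of composition might raise them. Fibroblasts or smooth muscle cells would bring their other abundant transcripts. The rise of ACTA2 (5.7 CPM) was 0.0125 of that of TAGLN (454.8 CPM), at most 0.039 at the ends of both intervals. The rise of LUM was 0.00072 of that of COL1A2, at most 0.0022. These genes were chosen after ACTA2 and LUM were seen to change little and TAGLN and COL1A2 to rise strongly. Low ratios were therefore likely in advance. They show that ACTA2 and LUM rose little beside TAGLN and COL1A2. They cannot decide whether cells of another type were present, so that explanation stays open. The 48 genes in the 3 lists had a median log2 fold change of 0.45. After removal of the trend in transcript length and GC content it was 0.53 (0.33 to 0.77 over resampled genes). Resampling treats the genes as independent, so this range may be too narrow. The blocked fit gave the same values from the same 6 libraries and adds no evidence. The median did not fall, which argues against a bias of length or GC content as the cause. A shift of the endothelial cells toward a contractile, matrix-producing state after SETD7 loss, an effect of the hairpin through other genes, and selection of a subpopulation during transduction stay open as hypotheses, and none of them was tested.

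Pseudogenes made up 522 of the called genes. Across 880 pseudogenes named after a tested protein-coding gene, the log2 fold changes of pseudogene and parent correlated at r = 0.716, where the highest of 1000 random pairings gave 0.115; with 1 pseudogene per parent r was 0.735 over 602 pairs. Genes are not independent replicates, so this r describes the table. Of 198 called pseudogenes with such a parent, 165 had a parent called in the same direction. Reads of the parent placed on the pseudogene are a likely source of much of this signal, as an unspliced aligner could do; transcription of the pseudogenes themselves was not tested.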
